A study of Homo sapiens with 4 samples.

How the data were processed

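The series profiled messenger RNA in 2 human lung cancer cell lines, A549 and H1299, each with a control culture and a culture in which RBM4, an RNA-binding protein that regulates splicing and translation, had been knocked down. There were 4 samples, with 1 library per group. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from total RNA with the Illumina TruSeq RNA Sample Prep Kit. Per the submitters' processing notes, CASAVA 1.8.2, TopHat and Cufflinks were used with genome build hg38. The role and order of these tools, the annotation release, any strand setting and any filter on reads were not given in the sources used here.

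The deposited values were FPKM (fragments scaled by transcript length and by the mapped fragments of the library), which the authors listed per protein-coding transcript with Ensembl transcript and gene identifiers. The unit was named by the file and fitted the values, which were not whole and added up to a different total in each library. Total counts were not given, so the depth of each library is unknown and no counting interval could be attached to any value. FPKM is relative to the rest of its library, and scaling beyond that definition was not stated.

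Columns were matched to samples by name alone, before the RBM4 values were read. In the A549 table the column with the bare name of the cell line was taken as the control, and the column that adds a number to that name was taken as the knockdown. The labels do not contain that number, so the direction of every comparison rests on this reading of the names. The H1299 table had 3 columns of values for 2 samples, under names that matched no label. These 3 columns were not used, and the 2 H1299 samples were not analysed here. The planned results that need H1299 were therefore not computed: its own counts of 2-fold genes, the genes shared by both lines, the correlation between lines, the limma model over both lines, the difference between lines, and genes ranked over both lines.

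From the deposited FPKM, transcripts were summed per gene symbol, which gave 19732 symbols, of which 26 combined 2 gene identifiers. Genes at 1 FPKM or more in either A549 library were kept, which left 12230. The difference of each gene was log2 of knockdown FPKM plus 1 over control FPKM plus 1, a scale that understates the difference of genes near 0. Genes with a difference of at least 2-fold on this scale were counted by direction. With 1 library per group there was no replicate error, no test of single genes was made, and no p-value is given.

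A total of 33 gene lists were fixed before the data were examined, together with the comparisons and most of the alternative settings. For each list the median difference of its measured members was placed among the medians of 10000 random lists of the same size, drawn from genes in the same 20 bins of mean expression. Medians at or below percentile 2.5 or at or above percentile 97.5 are called below or above the range of matched random lists. Such a percentile describes these libraries alone. Members of a list are often regulated together, so many lists can fall outside that range: 25 of the 33 did, against 1.65 expected for unrelated genes.

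Genes were named by a rule fixed beforehand: RBM4; the 10 highest and 10 lowest differences, leaving out small RNAs and unnamed loci; the 2 highest and 2 lowest members of each list, ranked here by the A549 difference in place of the mean over both lines; and, whatever their values, a fixed set that includes CDKN1A, CDKN2A, LMNB1, STK11, IL6, CXCL8, MDM2, RBM4B and RBM14. Some genes that this rule names are not reported here. Other list members named as examples were chosen after their values were seen. Gene positions, transcript lengths and GC content came from GENCODE release 29 on the same build, to which 99.5% of the transcripts matched by identifier. Genes whose exons overlap another gene on the same strand, and genes with near-identical copies, are uncertain because the sharing of reads between them is not known. Not all of them are marked where they are named below. RBM5, DNAJB4 and MCOLN1 share exons with another gene and are uncertain too.

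The count of 2-fold genes and the list percentiles were tested on simulated data made from the control library with 200 changed genes and noise of 0.3 (SD, log2). Of the genes simulated at 4-fold, 98% passed in the right direction, against 6% of those at 1.5-fold and 0.0173% of unchanged genes, among 11776 genes. The changed genes were drawn only from genes above the filter in the control library. The shares of 98% and 6% therefore do not cover genes near 0 in the control. Of 100 simulated unchanged lists of 30 genes, 8 fell outside the range, and all 50 lists shifted by 0.3 did. The noise level was assumed, since the libraries give no replicate to estimate it from, and it was the same for genes at every level. It is below the robust SD of the measured differences, 0.45, which holds noise and real differences together. The share of unchanged genes past 2-fold in the real libraries is therefore unknown.

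Alternatives were pseudocounts of 0.1 and 0.5 FPKM, no filter on low values, a minimum of 5 FPKM, rescaling both libraries to the same total (the TPM scale), centring the median difference at 0, the highest transcript per symbol in place of the sum, and random lists not matched on expression. A further 3 were added after the data were seen: removal of trends with transcript length and GC content by lowess with a span of 0.3, exclusion of the mitochondrial genome's genes from the scale, and exclusion of genes with shared exons. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.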

Results

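Gene expression was compared between a control library and an RBM4 knockdown library of A549, a human lung adenocarcinoma cell line, to ask which genes differ when RBM4 is reduced and, from the series title, how genes tied to cellular senescence behave. The series also describes a control and a knockdown sample of H1299, another human lung cancer line, which were not analysed here. The A549 comparison had 1 library per group, so no difference has a replicate check, and each value below is a measurement of 1 library. Which column was the knockdown was read from the column names alone. Values are FPKM as deposited, summed per gene over 79989 protein-coding transcripts, with totals of 671529 FPKM in the control and 622366 FPKM in the knockdown library, and the sequencing depth is unknown. Genes at 1 FPKM or more numbered 11702 in the control and 12067 in the knockdown library. Transcripts of the mitochondrial genome held 18.6% of all FPKM in the control and 21.7% in the knockdown library.

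RBM4 itself was lower in the library read as the knockdown. RBM4 (ENSG00000173933, chromosome 11, 66638617 to 66668374, plus strand, hg38) had 59.4 FPKM in the control and 30.6 FPKM in the knockdown library, which was 51.5% of the control and a log2 difference of -0.93. That difference was short of 2-fold, and 2.76% of all genes had a lower one. Of the 11 RBM4 transcripts listed, 7 were lower, and the most abundant in the control library, ENST00000310092, had 23.8 FPKM in the control and 8.04 FPKM in the knockdown library, 33.8% of the control. The neighbouring gene RBM14, joined to RBM4 by read-through transcripts that share exons with both, was also lower, at 46.4 and 25.8 FPKM (log2 difference -0.82), so the 2 genes' values are uncertain to the extent that reads were shared. The paralog RBM4B, which overlaps this locus on the minus strand, had 11.7 and 8.95 FPKM (-0.35).

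Beyond RBM4, the genes with the highest differences included ITGB3, TAGLN, CLDN4 and IL11, and those with the lowest included CPLX2, PTMA and HIST1H4K. The integrin subunit ITGB3 (ENSG00000259207, chromosome 17, 47253846 to 47311816, plus strand) had 0.93 FPKM in the control and 46.4 FPKM in the knockdown library, a log2 difference of 4.62, and the actin-binding protein TAGLN had 8.20 and 185.8 FPKM (4.34). The tight-junction gene CLDN4 (3.89), the focal adhesion gene TNS1 (3.84), the cytokine IL11 (3.68), GLIPR1 (3.59) and CGB5 (3.54) followed, the last belonging to a cluster of near-identical chorionic gonadotropin genes and therefore uncertain. LUZP6 was listed at 0 in the control and at 53.8 FPKM in the knockdown library, but it shares exons with MTPN and no fold is given.

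At the other end, CPLX2, a regulator of vesicle fusion, had 173.6 and 24.5 FPKM (-2.77), and PTMA, the prothymosin gene, which has many processed copies, had 1123 and 198.5 FPKM (-2.49). The remaining lowest genes were C10orf107 (-3.06), SMIM11B (-3.06), the histone gene HIST1H4K (-2.89), the nuclease gene EXOG (-2.33), TM4SF20 (-2.27), the exocyst gene EXOC6 (-2.27) and LAPTM4B (-2.15). SMIM11B has the near-identical copy SMIM11A, with 11.97 and 11.52 FPKM, and is uncertain. PIGY, which shares exons with PYURF, was at 3.70 FPKM in the control and listed at 0 in the knockdown library.

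In all, 882 of 12230 genes (7.21%) differed by at least 2-fold, 607 of them higher and 275 lower in the knockdown library, so that 68.8% were higher. At 4-fold or more, 87 genes were higher and 15 lower. The median difference over all genes was -0.04 with a robust SD of 0.45, and the libraries correlated at Pearson r = 0.952 across genes, which are not independent replicates. With a pseudocount of 0.1 the count was 1403. The split was 925 higher and 243 lower (79.2% higher) after rescaling both libraries to the same total, and 810 higher and 176 lower (82.2% higher) with mitochondrial genes left out, where the median of all genes moved to 0.07 and 0.11. In the other direction, it was 413 higher and 245 lower (62.8% higher) at a minimum of 5 FPKM. With the highest transcript per symbol it was 608 higher and 350 lower (63.5% higher). A total of 65 of the 2-fold genes share exons with another gene.

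**Figure D1:**
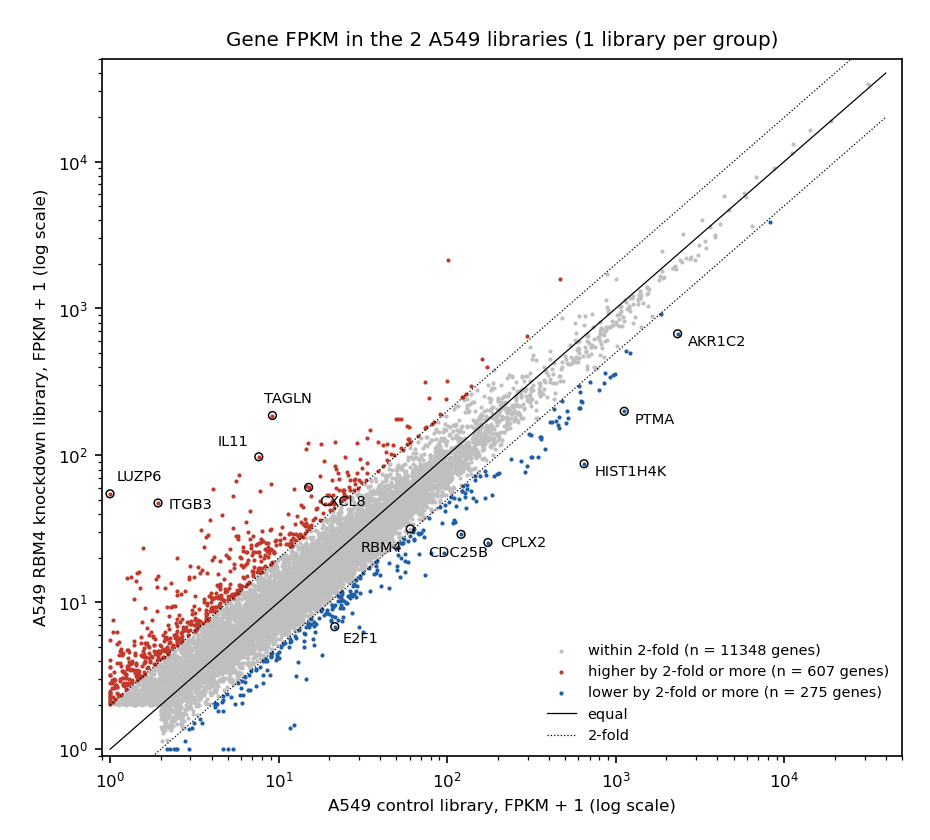
FPKM plus 1 of each of the 12230 genes in the A549 control library (horizontal axis, log scale) and the A549 RBM4 knockdown library (vertical axis, log scale), 1 library each; red points are the 607 genes higher and blue points the 275 genes lower by 2-fold or more, grey points the rest, and circles mark named genes. TAGLN lies far above the line of equal values at 8.20 and 185.8 FPKM, and RBM4 lies below it at 59.4 and 30.6 FPKM.

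Secreted factors of the senescence-associated secretory phenotype (SASP), the set of proteins that senescent cells release, were higher in the knockdown library. Of 54 listed members, 42 were measured. Their median log2 difference was 0.97, above all 10000 matched random lists, with 18 members higher and 1 lower by at least 2-fold and 37 above 0. IL11 had 6.63 and 96.8 FPKM (3.68), the neutrophil chemokine CXCL8 had 14.1 and 59.6 FPKM (2.01), the protease gene MMP2 had 4.35 and 31.2 FPKM (2.59), and the urokinase gene PLAU had 34.03 and 147 FPKM (2.08). IL6, a central SASP cytokine, was low in both libraries, at 1.63 and 4.70 FPKM (1.12). The cytokine genes IL1A and IL1B were below 1 FPKM in both libraries and so not among the measured members. The chemokine genes CXCL1 (0.13), CXCL2 (-0.12), CXCL3 (-0.32) and CXCL5 (0.17) differed little. Against the direction of the list, IGFBP3 had 54.9 and 15.0 FPKM (-1.80) and GDF15 had 45.2 and 23.2 FPKM (-0.94).

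Regulators of senescence were mixed, with 9 measured members above 0 and 15 below. The 24 measured members had a median of -0.41, below the range of matched random lists (percentile 0.15), with 1 member higher and 3 lower by at least 2-fold (2 higher and 1 lower with mitochondrial genes left out). The list joins cell-cycle inhibitors such as CDKN1A with genes such as LMNB1, whose loss marks senescent cells. Its median therefore speaks neither for nor against senescence. LMNB1, the lamin whose loss marks senescent cells, had 53.7 FPKM in the control and 24.4 FPKM in the knockdown library (-1.11). ID1, an inhibitor of differentiation factors, had 458 and 181 FPKM (-1.33), and ID2 had 131 and 62.3 FPKM (-1.06). The chromatin protein gene HMGA2 had 18.4 and 52.9 FPKM (1.48). CDKN1A, which encodes the cell-cycle inhibitor p21, had 73.6 and 132.7 FPKM (0.84), short of 2-fold. CDKN2A, which is deleted in A549 cells, was listed at 0 in both libraries.

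MDM2, a p53 target and antagonist, had 113.5 and 115.0 FPKM (0.02). The 32 p53 target genes had a median of 0.13 at percentile 97.6, on the edge of the range of matched random lists, and 4 were higher by 2-fold (6 with mitochondrial genes left out). The highest were SESN2 at 2.74 and 8.95 FPKM (1.41) and GADD45A at 16.0 and 42.9 FPKM (1.37), both stress sensors, and the lowest were GDF15 (-0.94) and AEN (-0.74). The list fell inside the range when random lists were not matched (percentile 95.6), when trends with length and GC content were removed (92.4) and when mitochondrial genes were left out (97.48).

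Genes of DNA replication and cell division were lower in the knockdown library. All 35 E2F target and DNA replication genes had a difference below 0 (34 with mitochondrial genes left out), with a median of -0.80 that lay below all 10000 matched random lists, and 7 were lower by at least 2-fold. The transcription factor gene E2F1 had 20.5 and 5.83 FPKM (-1.66), and the replicative helicase gene MCM6 had 43.9 and 17.4 FPKM (-1.29), while E2F7 (-0.12) and CDT1 (-0.26) lay closest to 0. The 35 G2 and mitosis genes had a median of -0.64, likewise below all random lists, with 6 lower by 2-fold and none higher (3 lower with mitochondrial genes left out). Among them the phosphatase gene CDC25B had 120 and 28.0 FPKM (-2.06), the transcription factor gene FOXM1 had 55.3 and 18.02 FPKM (-1.57), and the proliferation marker MKI67 had 76.6 and 36.5 FPKM (-1.05). ANLN (-0.11) and TTK (-0.18) differed least.

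Replication-dependent histone genes were lower by more. The 16 measured members had a median of -1.23, below all matched random lists, and 14 were lower by at least 2-fold (9 with mitochondrial genes left out). HIST1H4H had 795 and 279 FPKM (-1.51) and HIST1H2BD had 989 and 358 FPKM (-1.46), while HIST1H1C (-0.87) and HIST1H1E (-0.97) differed least. Histone genes are short and near-identical, so the level of a single one is uncertain. Recovery of histone transcripts at library preparation could not be told apart from cell cycle differences, a limit on the whole list.

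Mesenchymal and extracellular matrix genes were higher in the knockdown library by the largest median of any list with more than 3 measured members. The median over 28 genes was 1.52, above all 10000 matched random lists, with 18 higher and none lower by at least 2-fold. Beside ITGB3 and TAGLN, the basement-membrane collagen gene COL4A1 had 13.98 and 121 FPKM (3.03), the fibronectin receptor subunit ITGA5 had 13.6 and 109 FPKM (2.91), and N-cadherin, CDH2, had 21.4 and 75.4 FPKM (1.77). The transcription factor gene SNAI2 had 0.27 and 3.18 FPKM (1.72). VIM, the mesenchymal filament vimentin, had 650 and 769 FPKM (0.24), and the lowest members were the integrin gene ITGB1 at 762 and 391 FPKM (-0.96) and TWIST1 (-0.09).

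Epithelial genes were not lower as a group. Their median over 15 genes was 0.36 (percentile 99.6), with 3 higher and 1 lower by 2-fold (none lower after rescaling, after centring the median or with mitochondrial genes left out). CLDN4 and the keratin gene KRT19, at 29.6 and 64.9 FPKM (1.11), were highest. The abundant keratin genes KRT18, at 1853 and 912 FPKM (-1.02), and KRT8, at 1646 and 888 FPKM (-0.89), were lowest, and E-cadherin, CDH1, had 7.70 and 6.54 FPKM (-0.21).

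Markers of other cell types were few but some differed along with the matrix genes. Of 13 fibroblast genes, 3 were measured, with a median of 1.54 (percentile 99.9): THY1 had 5.73 and 26.0 FPKM (2.003), COL1A1 had 2.61 and 9.47 FPKM (1.54), and TWIST2 had 13.98 and 9.60 FPKM (-0.50). Of 16 blood and immune cell genes, 2 were measured, with a median of 1.26 (percentile 98.3), namely CD68 at 6.90 and 25.8 FPKM (1.76) and CD14 at 2.16 and 4.32 FPKM (0.75). The only measured endothelial gene of 9, ESAM, had 3.04 and 18.5 FPKM (2.27; percentile 99.9). Without the filter on low values the fibroblast and immune lists lay inside the range. The 4 measured alveolar and airway genes of 19 had a median of 0.22 (percentile 66.3), from TP63 (0.30) and ABCA3 (0.27) to LPCAT1 (0.16) and AGER (-0.13).

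**Figure D2:**
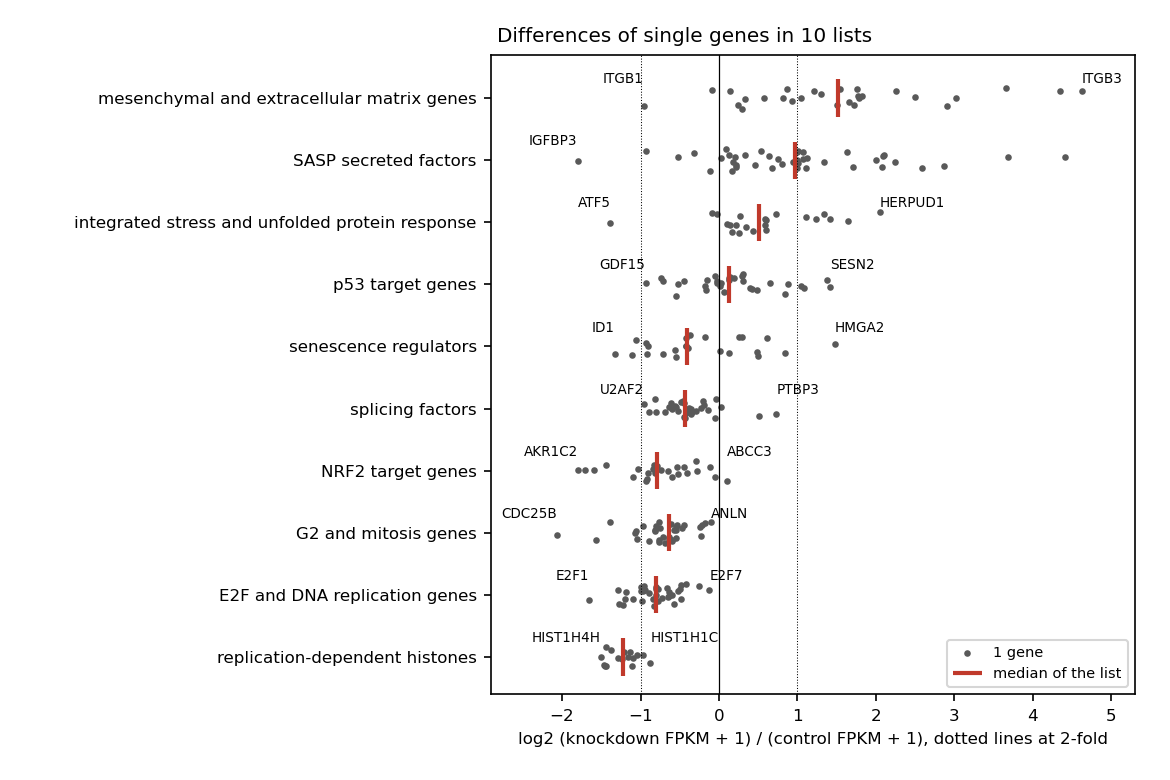
Log2 difference between the A549 knockdown and control libraries (horizontal axis) of each measured gene in 10 of the 33 lists (rows); grey points are single genes, red bars list medians, dotted lines 2-fold, and labels name the highest or the lowest genes of the lists. Matrix genes reach from -0.96 (ITGB1) to 4.62 (ITGB3), while all E2F and DNA replication genes lie below 0.

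Stress pathways differed in opposite directions. Genes of the integrated stress and unfolded protein responses had a median of 0.51 over 22 members, above all matched random lists, with 6 higher and 1 lower by 2-fold. HERPUD1, of protein degradation at the endoplasmic reticulum, had 28.3 and 120.4 FPKM (2.05), the transcription factor gene DDIT3 had 6.04 and 21.001 FPKM (1.64), and the chaperone gene HSPA5 had 137 and 296 FPKM (1.11), while ATF5 had 15.3 and 5.27 FPKM (-1.38) and PDIA6 lay at -0.08. Targets of the antioxidant factor NRF2 were lower: the median of 25 genes was -0.79, below all matched random lists, with 6 lower and none higher by 2-fold (4 lower after rescaling or with mitochondrial genes left out). AKR1C2, which has close paralogs, had 2328 and 671 FPKM (-1.79), OSGIN1, which shares exons with another gene, had 26.4 and 7.39 FPKM (-1.71), and the heme oxygenase gene HMOX1 had 110 and 35.6 FPKM (-1.60). ABCC3 (0.11) and TALDO1 (-0.06) were the highest members. Heat shock genes had a median of -0.49 over 14 members (percentile 0.21), with 3 lower by 2-fold, a number that became 0 after rescaling to the same total. The lowest were the near-identical pair HSPA1A (-1.10) and HSPA1B (-1.08), and DNAJB4 (0.25) and HSF1 (0.16) were highest.

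Splicing factors were modestly lower. Their median over 32 genes was -0.43 (percentile 0.02), 29 members had a difference below 0, and none differed by 2-fold. With mitochondrial genes left out the median was -0.27 and 26 members lay below 0. U2AF2, of 3' splice site recognition, had 120.4 and 61.8 FPKM (-0.95) and SRSF2 had 187 and 99.9 FPKM (-0.90), whereas PTBP3 had 57.8 and 96.7 FPKM (0.73) and MBNL2 had 20.2 and 29.2 FPKM (0.51). RBM4 and related RNA-binding proteins, 13 genes, had a median of -0.38 (percentile 1.93) that ran from RBM4 and RBM14 to RBM25 (0.04) and RBM5 (0.31). That list fell inside the range with length and GC trends removed (percentile 4.21) and with exon-sharing genes, RBM4 among them, left out (3.77). Total levels of 13 reported RBM4 splicing targets had a median of 0.01 (percentile 82.1), which turned to -0.08 with length and GC trends removed. Highest were the tropomyosin gene TPM1 at 295 and 646 FPKM (1.13) and the survival gene MCL1 at 52.2 and 111.7 FPKM (1.08). The lowest were the transcription factor gene TEAD4 at 22.8 and 10.3 FPKM (-1.07) and SRSF1 at 230.1 and 159.4 FPKM (-0.53). SRSF1 shares exons with another gene and is uncertain.

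The 26 ribosome biogenesis and MYC target genes had a median of -0.58, below all matched random lists, with 2 lower by 2-fold (1 after rescaling or with mitochondrial genes left out), the polyamine enzyme genes SRM (-1.26) and ODC1 (-1.07), and RRP12 (-0.07) and POLR1A (-0.33) differing least. The 34 cytosolic ribosomal protein genes had a median of -0.24, which lay within the range of matched random lists (percentile 43.9), from RPL11 (-0.88) and RPL18 (-0.51) to RPL10 (-0.09) and RPL27 (-0.06). The 19 housekeeping genes, chosen as a control, had a median of -0.33 (percentile 5.17), from TFRC (-0.56) and TBP (-0.48) to GUSB (0.13) and B2M (0.57). Small negative medians in other lists of abundant genes are of a size similar to that of these control genes.

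STK11, which encodes the kinase LKB1, had 18.7 and 19.97 FPKM (0.09), and the 28 genes of the LKB1, AMPK and mTORC1 pathway had a median of 0.03 (percentile 85.2). These transcript levels do not show whether functional LKB1 protein is made in these cells. PRKAB2 (1.10) and CAB39 (0.59) were highest, and RPS6KB1 (-0.77) and DDIT4 (-0.71) lowest. RPS6KB1 shares exons with another gene and is uncertain. In glutamine and amino acid metabolism the median of 21 genes was -0.19 (percentile 30.8), and -0.03 with mitochondrial genes left out. The amino acid transporter genes SLC7A5, at 507 and 165 FPKM (-1.61), and SLC3A2, at 312 and 137 FPKM (-1.18), whose products form 1 complex, were lowest, and the glutamine synthetase gene GLUL (0.57) was among the highest. Cholesterol synthesis genes had a median of -0.37 over 28 members (percentile 0.12), with MVK (-1.37) and HMGCS1 (-1.29) lower by 2-fold and STARD4 (0.74) and SCD (0.25) highest. Nuclear genes of the respiratory chain had a median of -0.34 over 30 members (percentile 1.37; inside the range at 5.92 with length and GC trends removed), from UQCRC1 (-1.60) and COX7C (-0.95) to SDHC (0.02) and NDUFB8 (-0.02). The 13 mitochondrial genome genes had a median of 0.07 (percentile 98.1), from MT-ND5 (0.36) and MT-CYB (0.30) to MT-ND1 (-0.04), and lay inside the range without matching on expression (76.8) and with exon-sharing genes left out (94.4). Their median was larger with length and GC trends removed, at 0.35 (percentile 99.8), and after rescaling, at 0.18. Hypoxia and glycolysis genes had a median of -0.13 over 30 members (percentile 40.6), which turned to 0.03 with mitochondrial genes left out, with PFKFB4, which shares exons with UCN2, at 2.11 and P4HA2 at 1.24, against ADM at -0.72.

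Interferon-stimulated genes, NF-kB targets and apoptosis regulators had medians above the range of matched random lists. Interferon-stimulated genes had a median of 0.42 over 34 members (percentile 99.98), with 6 higher by 2-fold, among them OASL at 0.27 and 2.53 FPKM (1.48) and IFITM3 at 2.63 and 8.9997 FPKM (1.46), and with IFI35 (-0.78) and IFIH1 (-0.60) lowest. NF-kB targets had a median of 0.28 over 23 members (percentile 99.8), with CXCL8 and LTB, at 0.17 and 2.70 FPKM (1.66), highest and BIRC3 (-0.27) and NFKBIA (-0.22) lowest. Apoptosis regulators had a median of 0.29 over 27 members (percentile 99.97), from the survival gene BCL2A1 (1.85) and the death-promoting gene BMF (1.45) to genes below 0 such as BIRC5 (-0.44). Immediate early genes had a median of 0.15 over 22 members (percentile 98.5), with JUNB (1.75) and JUN (1.29) highest and DUSP5 (-0.62) and MYC (-0.55) lowest, and fell inside the range without the filter (95.8), without matching (94.5) and with length and GC trends removed (96.8). Lysosome and autophagy genes had a median of 0.10 over 28 members (percentile 98.8; 91.7 without matching), with GABARAPL1 at 23.6 and 96.2 FPKM (1.98) and WIPI1 (0.99) highest and MCOLN1 (-0.48) and SQSTM1 (-0.43) lowest. YAP and TEAD targets went both ways, with a median of -0.16 over 20 members (percentile 28.9), 4 higher and 2 lower by 2-fold (1 lower after rescaling or with mitochondrial genes left out): NT5E had 16.7 and 71.1 FPKM (2.03) and F3 had 1.25 and 7.13 FPKM (1.86), while ANKRD1 had 17.2 and 3.40 FPKM (-2.05).

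**Figure D3:**
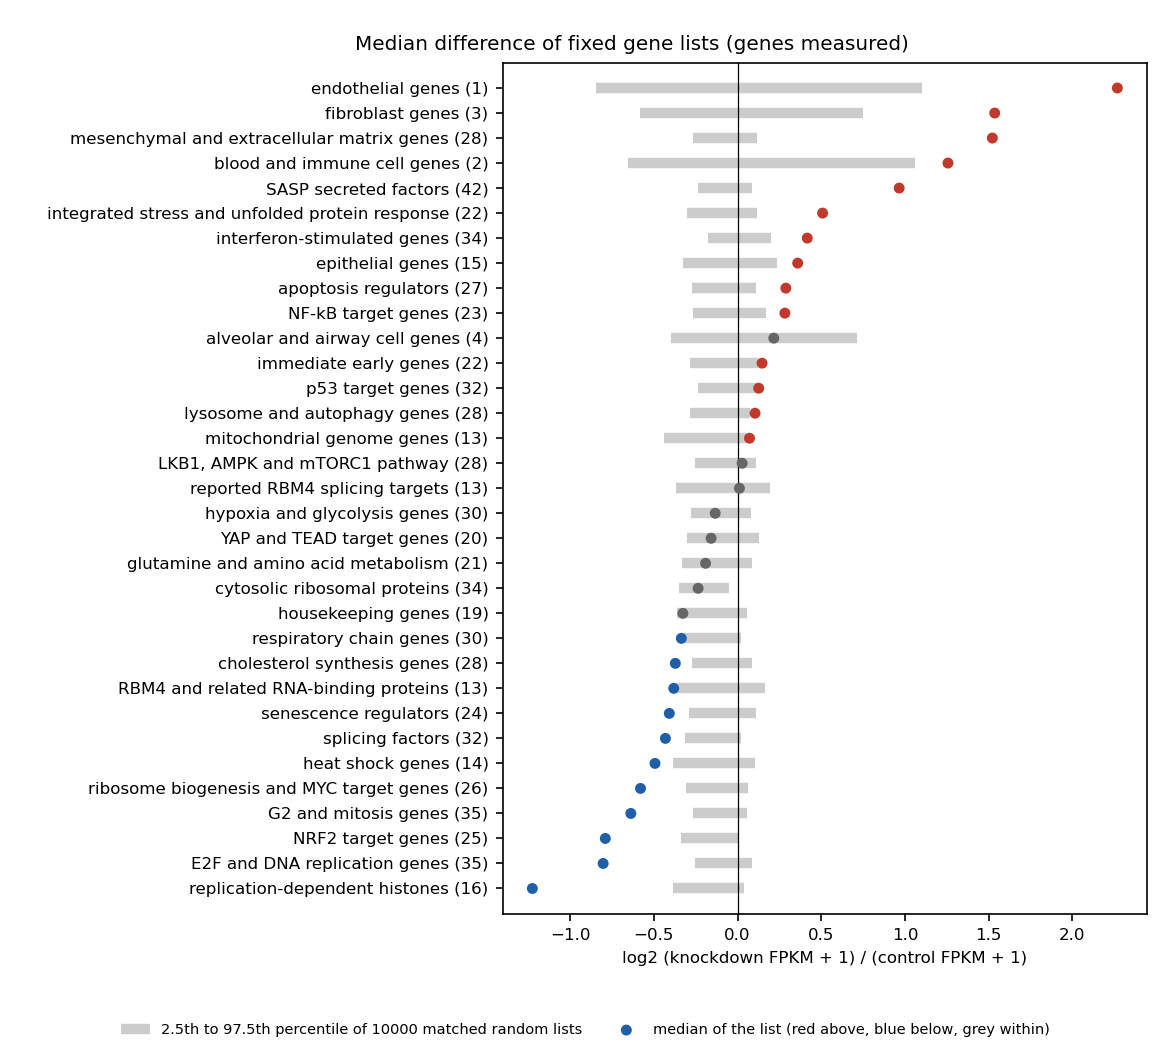
Median log2 difference between the A549 knockdown and control libraries (horizontal axis) of the 33 gene lists (rows, with the number of genes measured); grey bars span the range of 10000 random lists matched on expression, and points are red above, blue below and grey within that span. A total of 14 lists lie above, 11 below and 8 within it.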

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

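The 3 alternatives on trends, mitochondrial genes and shared exons were chosen after the data were seen. In the 11 alternatives run, no list that lay outside the range of matched random lists and no named gene past 2-fold changed sign, nor did RBM4. For 71 named genes past 2-fold, 14 of 702 values fell under 2-fold. With a pseudocount of 0.1 FPKM there were 1403 genes past 2-fold, 985 higher and 418 lower, because a smaller pseudocount enlarges differences of genes near 0. At a minimum of 5 FPKM the share higher was 62.8%. Rescaling both libraries to the same total gave 925 higher genes and 79.2% higher, and leaving mitochondrial genes out gave 176 lower genes and 82.2% higher. In the latter setting the median of all genes was 0.11 and small negative list medians shrank. Senescence regulators then had a median of -0.24, cholesterol synthesis genes -0.21 and respiratory chain genes -0.17. Rescaling also enlarged all values against the fixed pseudocount and filter (12728 genes passed), and the part of each was not tested. RBM4 taken as its highest transcript had a difference of -1.45. It was smaller than in the main setting after rescaling (-0.83), with length and GC trends removed (-0.84) and with mitochondrial genes left out (-0.77).

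Some lists that had lain outside the range lay inside it, and the cause was not tested. Without the filter on low values the medians were 0.094 for immediate early, 0.019 for fibroblast and 0 for blood and immune cell genes. Against unmatched random lists these were p53 targets (0.13), mitochondrial genome (0.072), lysosome and autophagy (0.10) and immediate early genes (0.15), while ribosomal protein (-0.24, percentile 1.45) and housekeeping genes (-0.33, 0.74) newly lay below it. With length and GC trends removed they were RBM4-related (-0.27), p53 target (0.11), respiratory chain (-0.19) and immediate early genes (0.15). With mitochondrial genes left out it was p53 targets (0.27), and with exon-sharing genes left out RBM4-related (-0.38) and mitochondrial genome genes (0.062). The other 346 list values kept their call, although medians of lists inside the range crossed 0: hypoxia and glycolysis genes from -0.13 to 0.03 with mitochondrial genes left out, reported RBM4 splicing targets from 0.01 to -0.08 with trends removed, -0.03 with the highest transcript and -0.01 without the filter, and the LKB1, AMPK and mTORC1 pathway from 0.03 to -0.01 at a minimum of 5 FPKM.

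No filter cannot change the count of 2-fold genes, since a gene under 1 FPKM in both libraries cannot reach 2-fold with a pseudocount of 1. Not run were the alternatives for H1299, for genes shared by the lines, for the correlation between lines and for the limma model over both lines, with and without the cell line as a block and with and without trend. No paired analysis was possible because the A549 comparison had 1 library per group. Depth is unknown, so the counting error of low values such as IL6 or LTB cannot be stated.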

Other observations

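The patterns weighed here were noticed among the genes with the highest and lowest differences before their tests were set. The test of histone recovery, those of cells in S phase or mitosis and of culture differences for the replication genes, the bootstrap interval for isoforms, and the grouping by gene family were chosen after the results were seen, as were the list of SMAD feedback genes and the test of its members without matrix and adhesion genes.

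Grouping genes by the letters that begin their symbols, with at least 3 letters and 8 measured members, gave 190 families, of which 20 lay below and 20 above the range of 2000 matched random lists, against 9.5 expected for unrelated genes. Collagen genes were higher as a family, with a median of 1.08 over 19 members, 11 of them by 2-fold or more and none lower by that much. Integrin alpha subunits had a median of 1.06 over 9 members, all above 0 and 5 past 2-fold, and tetraspanins, small membrane proteins, had 0.45 over 16. The histone family as a whole, which includes the 16 listed genes, had 50 of 58 measured members lower by 2-fold (42 with mitochondrial genes left out) and a median of -1.39.

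Some families lay below the range by small medians. The large-subunit proteins of the mitochondrial ribosome had a median of -0.40 over 49 genes and the small-subunit proteins -0.34 over 29. The LSM proteins of RNA processing had -0.55 over 13 genes, the tRNA methyltransferase family TRMT -0.42 over 16 and the exosome subunits -0.41 over 10. These medians stayed below 0 under each scaling tried, at -0.24, -0.19, -0.39, -0.28 and -0.25 with mitochondrial genes left out. In the main setting several are close to the -0.33 of the housekeeping genes, whose median was -0.16 with mitochondrial genes left out. Other families of RNA handling lay inside the range, among them DDX (-0.24, percentile 3.25), RRP (-0.27, 8.45), DHX (-0.23, 14.1), UTP (-0.19, 20.7), CNOT (-0.21, 24.5) and INTS (-0.08, 45.4).

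Matrix genes were higher in the knockdown library, with a median of 1.52. A trend with transcript length or GC content was argued against, since the list stayed at percentile 100 after its removal. Fibroblasts in the culture as the main source were argued against too, since COL1A1, COL1A2, COL3A1, DCN and LUM, abundant in those cells, together differed by 6.96 FPKM while COL4A1 differed by 107.1 FPKM. The 5 genes together were still higher, at 2.69 and 9.65 FPKM, so a small number of fibroblasts is not excluded. In the control library 3 of the 13 fibroblast genes reached 1 FPKM as well, and 3 stand in the matrix list. TGF-beta signalling, a known inducer of TAGLN and matrix genes, is a candidate explanation. The 14 genes listed as SMAD feedback genes, kept out of the other lists, had a median of 0.57 at percentile 100, with 10 members above 0 and 4 below. The list was chosen after the results were seen, and not all of its members are feedback inhibitors of SMAD signalling. Its percentile therefore does not single out this explanation. LTBP2 (1.43), LTBP3 (1.21) and TGFB1I1 (1.14) are matrix or adhesion genes themselves, so they partly restate the pattern; the other 11 had a median of 0.50 at percentile 99.95, with 7 above 0. Among these PMEPA1 (1.66) and BHLHE40 (1.13) passed 2-fold and SMAD7 (0.50) and SKIL (0.52) were modestly higher, but SMAD6 (-0.20), TGIF1 (-0.22), SKI (-0.57) and BAMBI (-0.62) were lower. RBM4 and any other difference between the cultures, such as density or passage, cannot be told apart with 1 library per group. The same holds for effects of the knockdown procedure on genes other than RBM4, which more libraries of the same kind would not separate.

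Replication genes were lower, with a median of -0.80. A trend with length or GC content was argued against, since the E2F list stayed at percentile 0 after its removal. Fewer cells in S phase or mitosis may explain the pattern, and the G2 and mitosis list was also at percentile 0. That percentile was known when the test was set and is part of the same pattern, so it is not separate evidence. Histone genes lay lower than the E2F list by a further difference of -0.42, and whether recovery of these transcripts adds to that cannot be told apart from cell cycle differences. With length and GC trends removed the histone median was -1.05 and the E2F median -0.77, a smaller gap. RBM4, other effects of the knockdown procedure and another difference between the cultures cannot be told apart here either, with 1 library per group.

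Isoform shares of reported RBM4 targets gave no answer. In 10 targets at 5 FPKM or more in both libraries, the median share of isoform signal that moved was 8.56%, at percentile 36.5 of random lists matched on expression and number of transcripts, whose median was 9.25%. The median of the targets lay below the 75th percentile of random lists (10.9%). By the rule set beforehand this counted against an effect of RBM4 level on their splicing. The bootstrap interval of the median, added after the results were seen, was 1.73% to 18.04% and reached past that percentile. It resamples the 10 genes and does not measure error in their shares. With that interval an effect was neither seen nor excluded. The largest shares moved were in the apoptosis genes BCL2L11 (31.8%) and BCL2L1 (19.0%) and in NUMB (18.04%). Shares estimated from single libraries are noisy, and RBM4 remained at 51.5% of the control.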
